A study of Mus musculus with 2 samples.

How the data were processed

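Total RNA of 1 wild-type and 1 mutant kidney sample from postnatal day 3 was hybridised to Affymetrix Mouse 430 2.0 arrays, per the labels. The series' design text states extraction with TRIzol, treatment with DNase I and analysis in dChip, the version of December 2010, and the sample labels state biotin labelling from 100 ng of RNA. The deposited values are intensity, the dChip expression index of each probe set on a linear scale, which the authors computed from the probes of each array. Per the file headers, the authors left out Affymetrix control probe sets, used the standard error for averaging, and gave a signed fold with lower and upper bounds. How background was subtracted, which array served as baseline and how the arrays were normalised are not given in the sources used here. These steps set the scale of dim values: 2.62% of probe sets in the wild-type array and 3.1% in the mutant array stood at exactly 1, so ratios of dim probe sets depend on a subtraction that cannot be checked.

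Both deposited files were compared. Their intensities were equal in all 45037 probe sets, and the signed fold was within 1% of the ratio of the arrays in 45027. The standard errors came from the model of the probes. Over the 16926 probe sets with both standard errors at 1 or more, intensity times standard error was nearly equal in both arrays (ratio 0.991 to 1.01), so the errors of a pair hold 1 quantity and say nothing of animals. In probe sets at or above the filter the median standard error was 1.76% of the wild-type value. The number of arrays limits the precision of every value.

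A probe set took its gene from the deposited annotation, with symbols updated by a RefSeq gene table. In all, 37579 probe sets named 1 gene, of which 34316 had a symbol in that table and 3263 kept the deposited symbol. The 1467 probe sets with several genes and the 5991 with none were left out, which removed Clu, Gapdh, Isg15 and Ren1 from the lists. Genes without a probe set of their own, such as Pax2 and Klhl3, were not analysed. No genome build is given for the arrays, so no positions are reported.

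Intensities were used as deposited, with no further scaling. Values under the 20th percentile of both arrays together (4.2) were set to it, log2 was taken, and the difference was mutant minus wild type. A fold against a value under the floor is given as at least that fold. A gene was kept if its brighter array reached the median of all values (16.53), and was represented by its probe set of highest mean log2 intensity. This gave 13146 of 20660 genes. Genes at least 2-fold apart were counted, with no test, since there was 1 array per group.

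Gene lists were described by the median log2 difference of the members above the filter, with a distribution-free binomial 95% interval that gives spread over genes and not replicate error. Each median was ranked among 10000 random lists of the same size, matched on mean intensity in 10 bins, and a list stood apart below the 2.5th or above the 97.5th percentile. Lists with under 5 kept members got values only. The 36 lists covered nephron segments (proximal tubule, loop of Henle, distal convoluted tubule, principal and intercalated cells), podocytes, nephron progenitors, early nephron, ureteric epithelium, stroma, endothelium, macrophages, lymphocytes, matrix, fibrosis, tubular injury and cell cycle. They also covered polycystic and cilium genes, cAMP, Wnt, Hedgehog, EGF receptor and renin angiotensin signalling, fatty acid oxidation, glycolysis, oxidative phosphorylation, p53, complement, interferon and immediate early genes. Erythroid, adrenal, adipose, muscle, liver and sex-linked lists stood for other tissues and for sex. Of 621 listed genes, 523 passed the filter.

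The named genes were the 12 with the largest difference in each direction, up to 4 members of each list with the largest absolute difference, and Bicc1, Pkd1, Pkd2, Pkhd1, Xist and Ddx3y whatever their values. Members named as exceptions to the direction of their list were chosen after their values were seen. They were Aqp2, Aqp3, Rhcg, Kl, Dpp4, Erg, Emcn, Esam, Vcam1, Afp and Ttr. The grouping, the lists, the rule for named genes, the filter, the thresholds and all alternatives but 1 were set before the data were examined. The alternatives were centring on array medians, quantile and loess scaling, no floor, a floor at the 40th percentile, a pseudocount of 32, no filter, a filter at the 75th percentile (83.51), the mean of all probe sets of a gene, and leaving out probe sets with the suffixes _x_at, _s_at and _a_at. Further ones were thresholds of 1.5-fold and 3-fold, all probe sets in 1 direction, the authors' lower bound, the values of the authors' table and random lists not matched on intensity. The count without the sex-linked and adrenal lists was added after the data were seen.

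The 2-fold rule and the list ranking were tested on simulated data of 13146 genes, 200 of them changed. The simulation used no floor and no filter, and its noise was held under 2-fold. Unchanged genes could therefore not be called, and the effects of floor, filter and dim values were not tested. The rule called 95.0% of genes changed 3-fold and 2.0% of genes changed 1.5-fold as 2-fold apart. Of 100 lists of 15 genes shifted by 0.3 on the log2 scale, 100 stood apart, and of 100 lists not shifted, 3 did. Members of these lists were drawn at random and varied independently. The 3 lists therefore give no rate of false calls for lists whose members vary together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.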

Results

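RNA was measured in kidneys of mice at postnatal day 3, when the kidney is still forming nephrons. A wild-type sample was set against a sample from the B6C3Fe a/a-bpck mutant, a mouse model of polycystic kidney disease, a disorder in which fluid-filled cysts form along the tubules. Each sample was read on 1 Affymetrix Mouse 430 2.0 array, a chip that measures each transcript with sets of short probes, so there were 2 arrays and no replicates. The labels do not state how many animals gave each sample, their sex, or which gene carries the mutation. The genotype label of the wild-type sample names no strain. The deposited intensities covered 45037 probe sets per array and summed to 5173132 in the wild-type array and 5175900 in the mutant array. Their medians were 16.97 and 16.13, and their highest values were 5568 and 5514. With 1 array per group the variation between animals is unknown and no test was possible, so every difference below describes these 2 arrays only.

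The comparison asked which kidney transcripts differed between mutant and wild type at this early postnatal stage of the disease. In the mutant array, markers of tubular injury, collecting duct principal cells, macrophages and cell division were mostly higher. Markers of podocytes, intercalated cells, the distal convoluted tubule and endothelium were mostly lower. Lcn2, an injury marker of the tubule, was 3.01-fold higher (intensity 41.7 in wild type and 125.5 in mutant). Avpr2, the vasopressin receptor of the collecting duct, was 1.69-fold higher (128 and 217), and Ptpro, a podocyte membrane phosphatase, was 1.53-fold lower on the brighter of its 2 probe sets (134 and 87.9). The log2 differences of those probe sets were -1.65 and -0.61. With each gene represented by 1 probe set, Xist was the gene farthest higher, and the steroid enzyme gene Hsd3b1 and the chromogranin genes Chgb and Chga were the 3 farthest lower.

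Of 13146 genes above the intensity filter, 69 were at least 2-fold higher in the mutant array and 68 at least 2-fold lower, together 1.04% of the genes. The near balance held with the intensities as deposited, while setting the array medians equal gave 87 higher and 48 lower. Most genes lay close together, with 78.9% within 1.2-fold, a median log2 difference of -0.01 and an SD across genes of 0.30. Many of the 137 genes were dim: among the 7786 genes whose brighter array reached the 75th percentile of intensity, 20 were at least 2-fold higher and 10 at least 2-fold lower. Without the members of the sex-linked and adrenal lists, 68 genes were higher and 61 lower. For genes with several probe sets above the filter, the SD of the log2 difference between probe sets had a median of 0.13 and a 95th percentile of 0.47 over 5269 genes. This spread is between probes on the same pair of samples and holds no variation between animals.

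**Figure D1:**
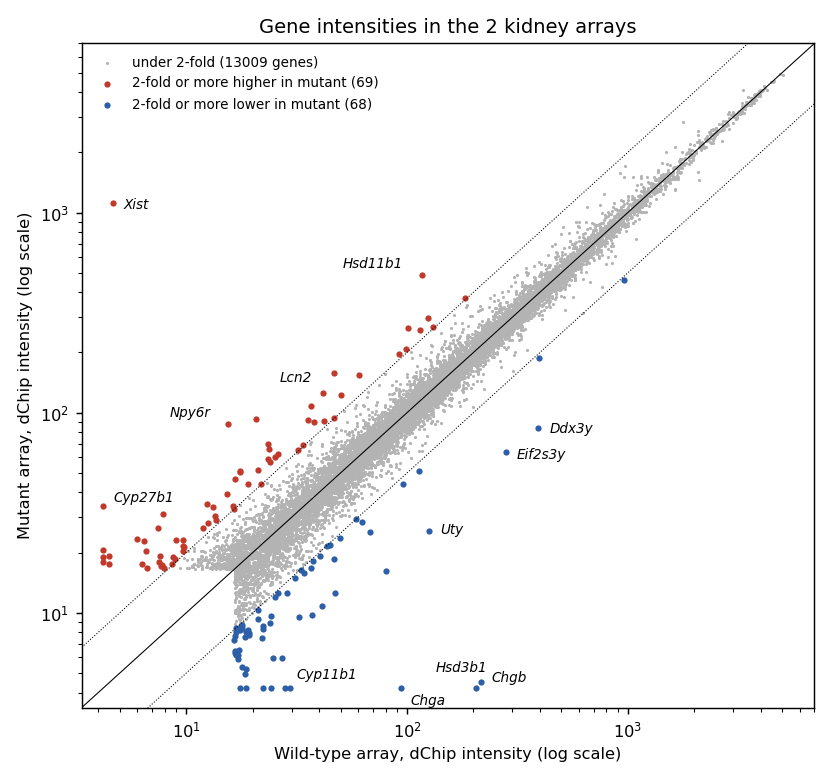
Intensity of each of the 13146 genes above the filter in the wild-type array (x axis, dChip intensity, log scale) and in the mutant array (y axis, the same unit and scale), 1 point per gene, with values under 4.2 drawn at 4.2. The solid line marks equal intensity and the dotted lines 2-fold differences, with 69 genes on or above the upper line in red and 68 on or below the lower line in blue, Xist lying farthest above and Hsd3b1, Chgb and Chga farthest below.

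Bicc1, the gene mutated in the jcpk and bpk strains of cystic mice, was measured by 3 probe sets, all higher in the mutant array by log2 differences of 0.36 to 0.46. The labels spell the strain bpck and name no mutated gene, so Bicc1 is not taken as the gene of this mutant. Its brightest probe set read 865 in wild type and 1117 in mutant, a 1.29-fold difference. Pkhd1, the gene of autosomal recessive polycystic kidney disease, was 1.49-fold higher (269 and 401). Pkd1 and Pkd2, the genes of the dominant disease, were within 1.02-fold (48.2 and 49.1) and 1.05-fold (530.2 and 557). Of the 25 measured polycystic and cilium genes, 16 were higher and 9 lower, with a median log2 difference of 0.04 (95% interval over genes -0.06 to 0.12), at percentile 88.5 of random lists of matched intensity. With array medians set equal, 19 of these genes were higher and 6 lower, with a median of 0.115. Ofd1, a basal body gene, was 1.26-fold lower with the intensities as deposited. Bbs4, a gene of the Bardet-Biedl complex, was 1.26-fold higher on its brightest probe set, but its probe sets ranged from -0.13 to 0.34 on the log2 scale.

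Sex-linked genes had the median farthest from 0 of any list. Xist, the RNA that coats the inactive X chromosome of females, read 4.67 in wild type and 1113 in mutant, 238-fold higher. All 3 of its probe sets differed in that direction, by log2 differences of at least 5.32 and, on the brightest, 7.90, the wild-type value lying under the floor in the other probe sets. The 4 Y-linked genes were lower in the mutant array: Kdm5d 4.93-fold (80.1 and 16.3), Uty 4.88-fold (125.7 and 25.8), Ddx3y 4.67-fold (394 and 84.2) and Eif2s3y 4.38-fold (279.7 and 63.8). The list's median was -2.22 and its mean -0.21, since Xist and the Y-linked genes went opposite ways, and its percentile was 0.0. Sex-linked expression and genotype thus differed together between the samples in every comparison reported here.

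Adrenal and neuroendocrine genes included the 3 genes farthest lower in the mutant array, Hsd3b1, Chgb and Chga. Hsd3b1 stood ahead of Chgb, while the floor leaves the place of Chga among them open. Hsd3b1, a steroid-synthesising enzyme, was at least 48.7-fold lower (204.7 and 2.77, the latter under the floor). Chromogranin genes, which encode proteins of hormone secretory granules, were lower as well: Chgb 47.9-fold (215.9 and 4.51) and Chga at least 22.4-fold (94.1 and 1.19). Scg2, another granule protein gene, was at least 6.70-fold lower and Cyp11b1, an enzyme of corticosteroid synthesis, at least 7.01-fold lower. All 7 adrenal list members above the filter were lower, with a median of -0.79 (95% interval -5.61 or lower to -0.29, percentile 0.0). Th, the rate-limiting enzyme of catecholamine synthesis, was 2.33-fold lower, and Star, which carries cholesterol into mitochondria for steroid synthesis, was 1.72-fold lower on its brightest probe set and at least 6.54-fold lower on the other above the filter. The kidney samples therefore also differed in adrenal transcripts, whose source the labels do not give.

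Among the other genes with the largest differences, Hsd11b1, which regenerates active glucocorticoid, was 4.16-fold higher in the mutant array (117 and 486). Cyp27b1, the enzyme that makes active vitamin D, was at least 8.18-fold higher (3.12 and 34.4), and the receptor gene Npy6r was 5.72-fold higher (15.4 and 88.1). Rhoh, Folh1 and Carmil2 were at least 4.92-fold, 4.51-fold and 4.29-fold higher, all from under the floor. The remaining genes among the 12 with the largest positive difference were 9130221J18Rik (4.49-fold), Mad1l1 (4.32-fold), Dlgap3 (3.95-fold), D030051J21Rik (3.94-fold) and 8430426J06Rik (3.92-fold). On the lower side stood Cd180, a B cell and macrophage receptor (at least 5.76-fold), Akr1cl (at least 5.28-fold), Dlk1 (4.58-fold) and Rbm12b2 (at least 4.46-fold). Apart from Hsd11b1, Npy6r and 9130221J18Rik, the genes in this paragraph stayed under the 75th percentile of intensity in both arrays.

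Nephron segments differed in opposite directions. Collecting duct principal cell genes were higher for 10 of 12 members, with a median of 0.34 (95% interval 0.04 to 0.57, percentile 100.0). Besides Avpr2, the water channel gene Aqp4 was 1.56-fold higher (305 and 476). The exceptions were Aqp2, the vasopressin-regulated water channel, with 843 in wild type and 681 in mutant, and Aqp3, with 182 and 158. Intercalated cell genes, whose products handle acid and base in the collecting duct, were lower for 10 of 11 members, with a median of -0.27 (-0.68 to -0.02, percentile 0.0), and for 8 of 11 with array medians set equal. Slc26a4, the chloride-bicarbonate exchanger pendrin, was 1.76-fold lower (113.8 and 64.6), and the exception, Rhcg, read 178 and 252. In the distal convoluted tubule list 7 of 8 members were lower, with a median of -0.30 (-0.68 to 0.26, percentile 0.0). There Slc12a3, the thiazide-sensitive sodium-chloride cotransporter, was 1.58-fold lower (307 and 194) and Slc8a1, a sodium-calcium exchanger, 1.60-fold lower (2 probe sets at -1.02 and -0.68 on the log2 scale), while Kl read 569.6 and 683.

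Podocyte genes were lower for 18 of 19 members, with a median of -0.37 (-0.54 to -0.07, percentile 0.0), and for 15 of 19 with array medians set equal. Besides Ptpro, the dimmer Rab3b was 1.73-fold lower (24.2 and 14.0) and Tdrd5 1.71-fold lower (17.8 and 10.4). The exception was Dpp4, with 629.9 in wild type and 722 in mutant on the brightest of 4 probe sets, which ranged from -0.15 to 0.20 on the log2 scale. Proximal tubule genes were mixed, with 21 of 35 higher, a median of 0.11 (-0.02 to 0.30) and percentile 100.0. Napsa, Slc3a1 and Hao2 were 1.71-fold, 1.65-fold and 1.57-fold higher, the probe sets of Napsa lying at 0.28 and 0.78 on the log2 scale, whereas G6pc, the last enzyme of glucose production, was 1.98-fold lower (625 and 317). The loop of Henle list stayed within the range of random lists, with 5 of 14 members higher, a median of -0.08 and percentile 4.2. Its largest difference was in Bsnd, a chloride channel subunit, 1.37-fold lower.

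**Figure D2:**
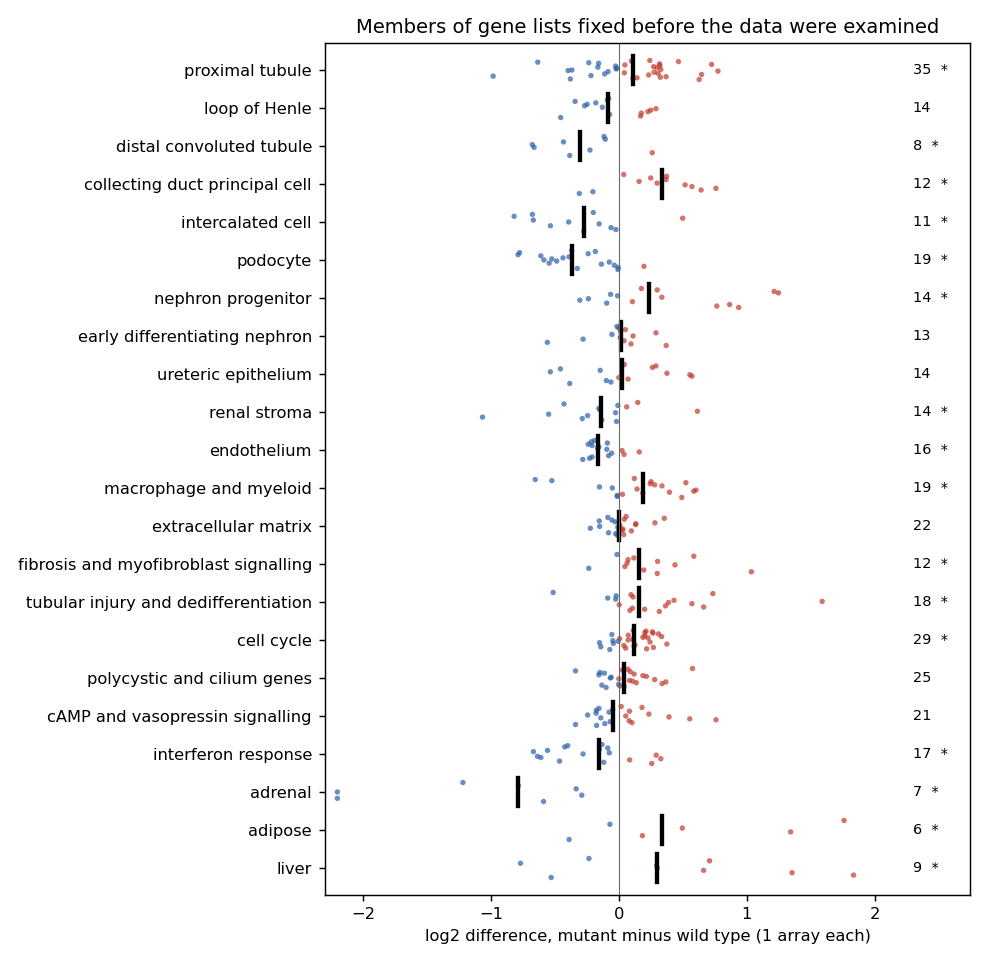
Log2 difference in intensity, mutant minus wild type (x axis), of each measured member of 22 gene lists (rows), 1 point per gene with the list median as a bar, 2 adrenal members beyond -2.2 being drawn at the edge. An asterisk marks the 16 lists whose median lay outside the middle 95% of random lists, among them podocyte (median -0.37) and collecting duct principal cell (median 0.34).

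Nephron progenitor genes were higher for 9 of 14 members, with a median of 0.24 (-0.09 to 0.94, percentile 100.0). Six2, the transcription factor that keeps nephron progenitors undifferentiated, was 2.38-fold higher (26.1 and 62.1), Spock2 2.32-fold (19.0 and 44.1), Crym 1.92-fold (104.4 and 199.9) and Gdnf, the signal that draws out the ureteric bud, 1.82-fold (13.7 and 25.0). This call rested on dim genes, since over the 7 members that reached the 75th percentile of intensity the median was -0.06. The early differentiating nephron list had a median of 0.02 (percentile 64.0), with 8 of 13 members higher and Cdh6 1.47-fold lower. In the ureteric epithelium list 8 of 14 members were higher, with a median of 0.02 (percentile 71.5). Krt7 was 1.49-fold higher there, and the uroplakin gene Upk1b 1.45-fold lower.

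Endothelial genes were lower for 13 of 16 members by small amounts, with a median of -0.16 (-0.22 to -0.06, percentile 0.0). With array medians set equal 12 were lower and the median was -0.09. Cd34 was 1.21-fold lower (235 and 193), and the exceptions Erg, Emcn and Esam were at most 1.12-fold higher. Stromal genes were lower for 11 of 14 members, with a median of -0.14 (-0.43 to 0.06, percentile 0.2). With array medians set equal 8 were lower and the median was -0.07. Dpt, a matrix protein gene, was 2.09-fold lower (49.5 and 23.7) and Lum, a collagen-binding proteoglycan gene, 1.46-fold lower, while Ntn1 was 1.53-fold higher. Extracellular matrix genes were divided, 11 higher and 11 lower, with a median of 0.00 and percentile 51.1, but 17 were higher and 5 lower, with a median of 0.08, when array medians were set equal. Their largest difference was in Timp1, an inhibitor of matrix proteases, 1.28-fold higher.

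Tubular injury genes were higher for 14 of 18 members, with a median of 0.16 (0.00 to 0.43, percentile 100.0). After Lcn2 came Tnfrsf12a, 1.67-fold higher (158 and 264), and the epithelial keratins Krt18, 1.58-fold (783 and 1241), and Krt7. Krt7 is also a member of the ureteric epithelium list. Of the 4 lower members Vcam1 differed most, 1.43-fold lower (222 and 156), with both probe sets lower (-0.51 and -0.38 on the log2 scale). Spp1 was within 1.07-fold, and the injury marker Havcr1 did not pass the filter. Among 12 genes of fibrosis and myofibroblast signalling 10 were higher, with a median of 0.16 (0.05 to 0.44, percentile 99.9). Ccn1, a secreted matricellular protein gene, was 2.05-fold higher (183 and 376), Thbs1 1.5-fold and Tagln, a smooth muscle gene, 1.36-fold. Without _x_at, _s_at and _a_at probe sets, the fibrosis percentile was 92.4, inside the range of random lists. Cell cycle genes were higher for 22 of 29 members, with a median of 0.12 (0.04 to 0.22, percentile 100.0). Pcna, the clamp of DNA replication, was 1.24-fold higher (1430 and 1773), Mcm6 1.26-fold and Ccne1 1.30-fold, and no member reached 1.5-fold.

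Macrophage and myeloid genes were higher for 13 of 19 members, with a median of 0.19 (-0.01 to 0.40, percentile 100.0). Csf1r, the receptor for the macrophage growth factor, was 1.52-fold higher (214 and 326, with 3 probe sets from 0.25 to 0.60 on the log2 scale) and Cd68 1.5-fold higher, whereas the neutrophil gene S100a9 was 1.57-fold lower. Interferon response genes were lower for 13 of 17 members, with a median of -0.15 (-0.46 to -0.07, percentile 1.3). Irf7, a transcription factor of the response, was 1.59-fold lower (42.2 and 26.6). Over the 7 interferon genes that reached the 75th percentile of intensity the median was 0.09, on the other side of 0. The complement and acute phase list had a median of 0.14 (percentile 97.1), with 8 of 12 members higher and C4b 1.53-fold lower. Only 4 lymphocyte genes passed the filter, too few for a percentile. Lck read 50.6 and 30.8, Ptprc 98.2 and 80.5, Ighm 15.3 and 17.3, and Cd79b 23.4 and 21.1.

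Signalling lists mostly stayed within the range of random lists, although single members stood out. Ihh, a hedgehog ligand, was 2.79-fold higher (12.5 and 34.9), and 8 of 11 Hedgehog genes were higher with a median of 0.10 (percentile 93.3). Btc, a ligand of the EGF receptor, was 1.82-fold higher, and 6 of 11 genes of that pathway were higher with a median of 0.03 (percentile 72.8). Egfr itself was 1.82-fold higher on its brightest probe set, but its 5 probe sets ranged from -0.33 to 0.87. In the cAMP and vasopressin list 10 of 21 members were higher, with a median of -0.05 (percentile 17.3), and Cftr, the chloride channel gene, was 1.47-fold higher. Wnt genes had a median of -0.03 (percentile 20.6), with 9 of 24 higher and the antagonist gene Dkk2 1.37-fold lower. For the renin angiotensin list the median was -0.08 (percentile 9.3), with 2 of 6 higher and Agtr2 1.23-fold lower. The p53 and apoptosis list had a median of 0.02 (percentile 68.6), yet it held Gdf15, a stress-induced cytokine gene, 2.80-fold higher (23.7 and 66.2), and the pro-apoptotic gene Pmaip1, 2.38-fold higher (38.0 and 90.3). Immediate early genes were higher for 11 of 15 members, with a median of 0.14 (-0.08 to 0.30, percentile 99.7). Fos was 1.77-fold and Atf3 1.59-fold higher. However, the list lay inside the random range over its members that reached the 75th percentile of intensity. It lay at percentile 83.6 without _x_at, _s_at and _a_at probe sets.

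In metabolism, glycolytic genes were higher for 13 of 16 members by small amounts, with a median of 0.11 (0.01 to 0.20, percentile 99.8). Pfkp, a phosphofructokinase, was 1.23-fold higher and Eno1 1.19-fold higher. Over the 8 members measured without _x_at, _s_at and _a_at probe sets, however, the percentile was 77.6. Fatty acid oxidation genes had a median of -0.04 (percentile 9.8), with 10 of 22 higher. Its member Cyp4a14, a fatty acid hydroxylase, was 2.10-fold lower (396 and 188). Oxidative phosphorylation genes had a median of 0.01 (percentile 63.9), with 12 of 23 higher. With array medians set equal 19 were higher and 4 lower, with a median of 0.09. Their largest difference in the intensities as deposited was in Uqcrc1, 1.14-fold lower.

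Markers of other tissues also differed. Adipose genes had a median of 0.34 over 6 members (-0.39 to 1.76, percentile 99.8), of which 4 were higher. Ucp1 and Cidea, genes of brown fat, were 3.39-fold (46.5 and 157.8) and 2.54-fold higher, whereas Adipoq was 1.31-fold lower. Liver genes had a median of 0.30 over 9 members (-0.53 to 1.36, percentile 99.9), 6 of them higher. Ahsg was 3.57-fold and Alb 2.56-fold higher, while Serpina1a was 1.70-fold lower. The 3 lower members, Ttr (2674 and 2275), Afp (796 and 552) and Serpina1a (223 and 131), were the brightest of the list. The higher median thus rested on dimmer members. Erythroid genes had a median of 0.13 over 6 members (percentile 92.4), 4 of them higher, with Tspan33 1.55-fold higher and Slc4a1, also an intercalated cell gene, 1.60-fold lower. Skeletal muscle genes had a median of 0.04 over 5 members (percentile 68.5), the largest difference being Mylpf, 1.16-fold lower. In all, 19 of the 35 lists with a percentile stood outside the random range, 11 higher and 8 lower in the mutant array, where 1.8 lists of unrelated genes would. Setting the array medians equal added to every difference. Among lists that stood apart, it moved further medians by over 1.5 times. They became 0.18 for proximal tubule, 0.28 for tubular injury, 0.19 for cell cycle, 0.18 for glycolysis, 0.22 for immediate early genes and -0.08 for the interferon response. The 19 lists still stood apart with array medians equal. This was nearly fixed in advance, since the random lists shift by almost the same amount. The medians of the cAMP, Wnt and fatty acid oxidation lists, which did not stand apart, turned to 0.06, 0.04 and 0.03. Members of a list vary together, so such a count describes the 2 samples and not the genotypes.

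The authors' deposited table gave the same intensities, with a fold and bounds for each probe set. Its fold for Xist was 238 with bounds 144.7 and 674, for Hsd11b1 4.16 with bounds 3.92 and 4.42, and for Bicc1 1.29 with bounds 1.26 and 1.32. These bounds rest on the model of the probes and hold no variation between animals. The last line of the table stated that 354 genes passed a fold of 1.5 with a difference of 20 intensity units. Counted over the probe sets listed, 351 had a fold above 1.5 and a difference above 20, and 256 had a lower bound above 1.5 and that difference.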

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

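The tests on sex-linked genes, on the noise of dim adrenal probe sets and on a chance draw of podocyte genes were chosen only after the result was seen. The other tests in this part were set before their values were known.

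A probe set annotated to Tgm2, transglutaminase 2, read 6.02 in wild type and 3839 in mutant, 637.7-fold higher, and stood out because the gene was represented by another probe set. The other 5 probe sets of Tgm2 were 1.07-fold to 1.18-fold higher. Further bright probe sets outside the gene comparison were at least 2-fold higher in the mutant array. They were 1 probe set each of Gpt2 (2.3-fold), Aplp2 (2.11-fold) and Smad4 (2.09-fold). Another 3 were of transcript clusters without a gene name (4.53-fold, 2.13-fold and 2.08-fold). The probe sets that represented Gpt2, Aplp2 and Smad4 in the gene comparison were under 2-fold apart. Bright probe sets lower in the mutant array were not searched for.

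Xist was higher and Y-linked genes were lower in the mutant array, but not down to the floor. A difference in the sex of the animals may account for the direction. On 1 probe set per gene, 4 X-linked genes that escape inactivation had a median log2 difference of 0.22, from 0.03 for Ddx3x to 0.54 for Eif2s3x. Single probe sets above the filter were less uniform, from -1.347 to 1.145 for Kdm5c and from -0.036 to 0.026 for Ddx3x. The 7 Y-linked probe sets above the filter kept 18.9% to 30.8% of their wild-type intensity, a 1.63-fold range, while their mutant intensities ranged from 7.27 to 84.2. Nonspecific background unrelated to the wild-type intensity, which would leave unlike shares, was argued against by that range, with bounds set after the values were seen. Nonspecific signal that rises with the wild-type intensity was not excluded. RNA of male animals in the mutant sample, as from a pool, could give it, and the labels do not say whether animals were pooled.

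All 7 adrenal genes above the filter were lower in the mutant array, and of all 12 listed, 11 were lower. Noise of dim probe sets was argued against by the percentile already reported for this list, fixed in advance (0.0 among 10000 lists of matched intensity). That percentile adds no independent evidence. Hsd3b1 was not dim in wild type (204.7, where the 75th percentile of intensity was 83.51). Adrenal tissue carried over into the wild-type sample may account for it, but in a second adrenal list 66.7% of members (10 of 15) were lower, short of the 75 percent set for it and above the 50 percent set against it. Of its 8 members above the filter 7 were lower, among them Slc18a1 (178 and 154) and Npy (92.3 and 52.2), and Ddc, which the kidney also makes, was higher (123 and 144). Carry-over, an effect of genotype and a difference in sex cannot be told apart with 1 sample per group.

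Podocyte genes were lower for 18 of 19 members. The median nearest to 0 under the other scalings was -0.30 (median centring, quantile and loess). These scalings moved the median of all genes only to 0.067, 0.002 and 0.005, so they could hardly bring this list near 0. The result shows only that these scalings did not remove the difference. A draw of unrelated genes was argued against by the percentile already reported for this list, fixed in advance (0.0, and 0.0 under all 12 alternatives), which adds no independent evidence and leaves open that its members vary together for another reason than genotype. Whether podocyte genes outside the list share the difference stays open, since in a second podocyte list 66.7% of members (12 of 18) were lower, with a median of -0.12, between the bounds of 50 and 75 percent set beforehand. A smaller share of glomeruli in the mutant sample, the biological candidate explanation, stays open for the same reason. Over the 17 members of the second list above the filter, 11 were lower and the median was -0.085.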

How the results depend on the processing

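The alternative without the sex-linked and adrenal lists was chosen after the data were seen, and all others before. Of 1646 values of 158 named genes under the alternatives, 1486 moved by no more than the median SD between probe sets (0.13) and 160 moved further. Part of this was fixed in advance. Both changes of filter and the authors' values could not move the value of a gene. Leaving out the floor could move only genes with a value under it. Of the 1646 values 8 changed sign, in genes under 2-fold apart, and 0 in genes at least 2-fold apart. Counts of genes 2-fold apart followed the treatment of dim genes. Lower genes numbered 44 with a floor at the 40th percentile. A pseudocount of 32 left 10 higher and 8 lower (18 in all), no filter gave 252 and 315 (567), and the filter at the 75th percentile gave 20 and 10 (30). By their construction, other thresholds gave 264 and 338 (602) at 1.5-fold and 17 and 22 (39) at 3-fold. The other alternatives gave 98 to 137 genes, but scaling shifted their balance, to 87 higher and 48 lower with array medians equal, 80 and 50 with quantile and 80 and 51 with loess scaling. Under quantile scaling 119 of the 137 genes were shared. Centring on array medians moved the median of all genes to 0.07 and raised list medians by similar amounts, as given beside the lists. With a pseudocount of 32 medians came nearer 0, to -0.18 for intercalated cells, 0.12 for nephron progenitors, -0.34 for adrenal, 0.17 for adipose, 0.15 for liver and -1.45 for sex-linked genes. Of the 19 lists that stood apart, 14 did so under every alternative that left at least 5 members. Centring on array medians and the authors' values could hardly change these percentiles. The adrenal, adipose, liver and sex-linked lists kept under 5 members at the 75th percentile filter and were not ranked there. With the filter at the 75th percentile the nephron progenitor median became -0.064 (percentile 21.2) and the interferon median 0.085 (percentile 90.2), each over 7 members, and the cause was not tested beyond the loss of dim members. Fibrosis, glycolysis and immediate early genes no longer stood apart without _x_at, _s_at and _a_at probe sets, nor did immediate early genes with the stricter filter. Leaving out replicates was not possible with 1 array per group. Signal over background limits the dim genes, but the floor does not measure how far. At or under it lay 8719 wild-type and 9316 mutant probe sets, a total fixed by setting the floor at the 20th percentile of both arrays together.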

Other observations

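The vitamin D list and the test of neighbouring genes were not part of the comparisons, and the list was written after Cyp27b1 had been seen among the largest differences. Beside Cyp27b1, at least 8.18-fold higher in the mutant array, Cyp24a1, which inactivates vitamin D, was 1.51-fold lower (848 and 561), and its second probe set read 31.0 and 18.4. Calb1, a calcium-binding protein gene of the distal tubule, was 1.30-fold lower, with 4 probe sets from -0.91 to -0.21 on the log2 scale. Other genes of mineral handling differed little: S100g read 3413 and 3427 and Kl 569.6 and 683, the receptor gene Vdr was 1.08-fold lower and the phosphate transporter gene Slc34a1 1.25-fold higher. Of the 11 genes of the list, 5 were lower and 6 higher, with a median of 0.01.

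Klk1, tissue kallikrein of the distal nephron, was among the brightest genes 2-fold apart, 2.09-fold lower in the mutant array (958 and 458), with both probe sets lower by similar amounts (-1.06 and -1.02). Among bright genes higher in the mutant array were Anpep, a brush border peptidase gene (124 and 297, 2.4-fold), and Aldh1a1, a retinaldehyde dehydrogenase gene (42.0 and 91.3, 2.17-fold). These genes were chosen after their values were seen.

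Some genes with large differences lay beside each other in gene order, such as Spink12 (2.94-fold higher) and Npy6r, or Rbm12b2 and Pdp1, both lower. A chromosome segment that differs between the animals could give such pairs, and the test was set before its result was seen. Among 12575 genes, of which 513 were at least 1.5-fold apart, 11 neighbouring pairs differed in 1 direction. Over 10000 shuffles of the genes the median was 10 pairs and the upper end of the middle 95% was 16. Across all chromosomes the pairs were thus no more frequent than in shuffled order. A single segment would add only a few pairs to such a count, so the test cannot exclude it and that explanation stays open.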
